A study of Mus musculus with 3 samples.

How the data were processed

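Gene counts of 3 mouse lung libraries were used, 1 library per mouse. Total RNA was extracted with a Direct-zol MicroPrep kit and libraries were made with a Nugen Universal mRNA Prep kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.17, Trim Galore 0.6.2, STAR 2.5.2a and the mouse build mm10. The counting tool, its gene annotation and its use of strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, nor reads shared by near-identical genes. The deposited values are raw counts per Ensembl gene, whole numbers with no normalization by the authors, in 1 column per mouse. The table held 53342 genes. Gene symbols, coordinates and exon lengths came from GENCODE release M21 of the same build, which matched 53237 identifiers (99.8%) holding 99.99% of all counts, and 105 identifiers had no match. Genes of the mitochondrial chromosome were not analysed here. Coordinates are 1-based.

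Library totals were 43845715, 35674761 and 31579465 counts for mice 4, 5 and 6, so that 1 count equals 0.0232, 0.0277 and 0.0315 CPM, and 27586, 26578 and 26696 genes had at least 1 count. CPM were scaled with TMM factors of 0.982, 1.01 and 1.004, and logs were taken as log2(CPM + 0.5). The mice are separate animals by their labels. All 3 belong to 1 labelled group, so no contrast between groups was fitted, and with 3 samples no outlier test was run.

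Spread between mice was tested gene by gene in edgeR 4.0.16 under R 4.3.3, with the filterByExpr filter (17636 genes kept), the older quasi-likelihood fit with robust empirical Bayes and a design with an intercept alone. Each gene's residual quasi-dispersion was set against the fitted trend by an upper-tail F test with 3.88 prior degrees of freedom, with Benjamini-Hochberg adjustment and a threshold of 0.05. For a gene list, the median log2 ratio of dispersion to trend was placed among 10000 random lists of the same size matched in 20 expression bins (two-sided resampling p, adjusted over the 45 lists with at least 3 tested members). The smallest p that resampling could give was 2e-04. The level of a list is the median over its members, as CPM or log2(CPM + 0.5), and detection means 1 CPM in each mouse. Differences between lists within a mouse were tested with an exact two-sided sign-flip test, whose smallest p with 3 mice is 0.25. Limma 3.58.1 and DESeq2 1.42.0 were alternatives. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for levels and intervals. Poisson intervals are exact at 95%, and 3 counts were taken as the floor for a count of 0. Reads carry no molecular identifiers in the values used, so Poisson intervals cover counting error only. Bootstrap intervals came from 10000 draws of list members within 1 pair of libraries. They measure spread among genes, which tend to vary together, and not spread among mice.

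The design, the alternatives and the gene lists (47 lists with 390 distinct genes, all found in the table) were fixed before the data were examined. They cover the GHRH axis, helper T cell programmes, regulatory T cell and checkpoint genes, granuloma, mycobacterial recognition, inflammasome, macrophage activation and matrix genes. Also covered are class II, type I interferon, reactive oxygen, cell cycle, immediate early, clock, glucocorticoid and heat shock genes. The rest are markers of lung, blood, immune and other cell types that the lung sample or its dissection could hold. Genes named are the 25 with the highest mean CPM, most of the 10 with the smallest p if none passed, every GHRH axis gene, up to 4 of the most abundant members of each other list and the sex-linked genes, and any other is a choice made after values were seen. Alternatives were other scaling, filters, dispersion estimates and tools, other pseudocounts, length scaling, list means, unmatched random lists and leaving out each mouse.

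The test was tried on simulated counts of 17636 genes with 200 shifted in 1 mouse, 50 at each of 2-, 4-, 8- and 16-fold. With every gene on the fitted trend, it found 27, 47, 50 and 50 of 50 and made 9 false calls. With the spread fitted in the real libraries it found 0 of 50 at each size. With no change simulated, 1 list passed. With 1 list shifted 3-fold in 1 mouse, 2 lists passed, the shifted list among them. Genes were simulated independently, so list members did not vary together as they tend to in real libraries.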

Results

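Bulk RNA sequencing counts were obtained from the lungs of 3 male C57Bl/6 mice, named here mouse 4, 5 and 6 after the digit in each label. Every mouse received microparticles made from Mycobacterium abscessus by the intratracheal route, in 50 µL at a dose equal to 1000000 bacteria, a challenge given to make granulomas form in the lung. Each was then given 5 µg of MIA-602, an antagonist of the growth hormone-releasing hormone (GHRH) receptor, under the skin daily for 3 weeks. The series concerns the activity of this antagonist in a model of sarcoidosis. All 3 samples carry the same label and form 1 group, and challenged mice without the drug were not analysed here, so no effect of the challenge or of the drug can be read from these values. The libraries held 43845715, 35674761 and 31579465 counts in mice 4, 5 and 6. Levels are given in CPM (counts scaled to a common library size of 1000000) as the mean ± SD over the 3 mice (n = 3), or for mice 4, 5 and 6 in that order.

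The male label of the mice was matched by their transcripts. The Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty stood at 77.8 ± 3.89, 53.1 ± 5.39, 29.9 ± 1.45 and 13.9 ± 1.08 CPM, and Xist, the RNA that silences 1 X chromosome in female cells, had 10, 4 and 7 counts. Across 17636 genes the libraries correlated with Pearson's r of 0.987 between mice 4 and 5, 0.991 between mice 4 and 6, and 0.992 between mice 5 and 6. These are correlations across genes, which are not independent replicates. More than 2-fold differences separated mice 4 and 5 at 448 genes, mice 4 and 6 at 288, and mice 5 and 6 at 117. A chi-square test of the counts gave 94.3, 49.5 and 36.6 per degree of freedom for these pairs, where counting noise alone would give values near 1, so no library was a copy or a second run of another. That the mice are separate animals is known from the labels.

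Surfactant, secretory, antigen-presenting and macrophage transcripts led the lung libraries. Sftpc, surfactant protein C of the alveolar type 2 cell (ENSMUSG00000022097, chromosome 14, 70520949 to 70524081), had the highest mean at 17704 ± 2887 CPM, followed by Scgb1a1, the secretoglobin of club cells (ENSMUSG00000024653, chromosome 19, 9083636 to 9087958), at 16153 ± 7481 CPM. This order rests on mouse 4, since Sftpc stood at 14532, 20177 and 18402 CPM and Scgb1a1 at 7643, 21691 and 19127 in mice 4, 5 and 6, and per kilobase of exon Scgb1a1 led. Lyz2, the lysozyme of macrophages and neutrophils, reached 10455 ± 1242 CPM, and the iron-storage subunits Fth1 and Ftl1 8124 ± 2029.7 and 2252 ± 334 CPM. MHC genes and their partners took 7 of the 25 highest places. Cd74 stood at 7075 ± 1705 CPM, B2m at 5858 ± 1256, H2-K1 at 5028 ± 691, H2-D1 at 4609 ± 763, H2-Ab1 at 3609.8 ± 812, H2-Aa at 3469.8 ± 699 and H2-Eb1 at 2475 ± 548 CPM. The other surfactant genes Sftpa1 and Sftpb had 3563 ± 187 and 2983 ± 621 CPM, the lysosomal genes Psap and Ctss 3602 ± 779 and 2743 ± 833, and Apoe and complement C3 2379 ± 685 and 2006 ± 379 CPM. Actb, Tmsb4x, Eef1a1 and Tpt1, genes of the cytoskeleton and of growth and translation, lay between 2301 and 7498 CPM, and Cbr2 and the nuclear RNA Neat1 at 2282 ± 927 and 2099 ± 87.0. Gm42418, a feature over the ribosomal RNA region of chromosome 17 (39846958 to 39848788), ranged from 1644 CPM in mouse 5 to 5546 in mouse 6 and can hold ribosomal RNA reads. The 25 genes with the most counts, taken library by library, held 12.8%, 12.8% and 13.4% of the counts of mice 4, 5 and 6. Of the 25 genes with the highest mean CPM, 19 were also among the 25 highest per kilobase of exon. H2-K1 and H2-D1 are near-identical in part, so reads may have been split between them.

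The receptor that MIA-602 blocks was close to the limit of detection in whole lung. Ghrhr, the GHRH receptor (ENSMUSG00000004654, chromosome 6, 55376295 to 55388530), had 4, 2 and 3 counts, or 0.0811 CPM over the summed libraries, with an interval of 0.0371 to 0.154 (95% exact Poisson). Its ligand Ghrh had 1, 6 and 8 counts (0.135 CPM over the summed libraries, with an interval of 0.0757 to 0.223) and growth hormone, Gh, 1, 5 and 5. The axis downstream of growth hormone was well expressed. The growth hormone receptor Ghr stood at 46.1 ± 10.3 CPM, insulin-like growth factor Igf1 at 58.5 ± 8.31, its receptor Igf1r at 52.2 ± 10.4 and its binding protein Igfbp3 at 61.0 ± 3.92 CPM. Receptors related to Ghrhr were low, with Vipr2 at 7.15 ± 1.35, Vipr1 at 5.11 ± 0.790 and Adcyap1r1 at 3.10 ± 0.519 CPM, and Vip, the peptide, at 0.654 ± 0.238. Ghrl, the ghrelin gene, stood at 1.74 ± 0.632 CPM, while its receptor Ghsr had 0 counts in every library, which allows up to 0.0696, 0.0830 and 0.0946 CPM in mice 4, 5 and 6 (3 counts each). Of the somatostatin system, which opposes GHRH, Sstr2 and Sstr4 had 1.05 ± 0.171 and 0.797 ± 0.0546 CPM, Sstr3 6, 3 and 6 counts, Sstr5 2, 1 and 0, Sstr1 0, 0 and 1 and Sst 0, 1 and 0. In all, 8 of the 19 axis genes reached 1 CPM in every mouse. Intervals and floors cover counting error only.

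Genes of the Th1 and interferon-gamma response lay above those of the type 2 and type 17 helper programmes in all 3 lungs. The median member of the Th1 and interferon-gamma list lay above the Th2 list by 2.57 ± 0.04 on the log2(CPM + 0.5) scale and above the Th17 list by 2.62 ± 0.20 (SD, n = 3, higher in 3 of 3 mice each). Gbp2, a guanylate-binding protein induced by interferon-gamma, stood at 861 ± 151 CPM, the chemokine Cxcl9 at 703 ± 172, the transcription factor Irf1 at 435 ± 71.6, and the immunity-related GTPases Igtp and Irgm1 at 419.7 ± 91.8 and 257 ± 46.0 CPM. In the Th2 list, the receptor chain Il4ra and Stat6 reached 162 ± 12.6 and 159 ± 10.4 CPM, the alarmin Il33 95.1 ± 8.44 and Gata3 13.8 ± 2.58. In the Th17 list, Stat3 had 253 ± 18.02 CPM, Il17ra 86.4 ± 6.84 and Batf 24.9 ± 3.12. The signature cytokines, chosen after their values were seen, were further apart. Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892) had 419, 235 and 390 counts, against 5, 1 and 0 for Il4, 7, 5 and 3 for Il5, 1, 0 and 0 for Il13 and 21, 6 and 18 for Il17a. Summed over the libraries, Ifng had 69.6 times the counts of Il5 and 23.2 times those of Il17a. The exact two-sided sign-flip test over 3 mice gave p = 0.25 for both differences, the smallest it can give, so none could pass. With members below the expression filter left out, the differences shrank to 1.16 and 0.40, so they rest in large part on the scarce Th2 and Th17 cytokines. Th2 and Th17 lists differed by 0.05 ± 0.17 (exact sign-flip p = 1, higher in 1 of 3 mice), within the spread between mice, and this difference turned negative without mouse 6 (−0.043).

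Classical macrophage activation exceeded alternative activation in every lung, by 2.06 ± 0.50 on the log2 scale (SD, n = 3, higher in 3 of 3 mice). Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), stood at 538, 219 and 277 CPM in mice 4, 5 and 6, whereas Arg1, the arginase that marks alternative activation, had 116, 82 and 62 counts. In each mouse Nos2 counts were 199.8, 96.7 and 142 times those of Arg1, a pair chosen after its values were seen. Irf5, Cd86 and Il1b had 131 ± 21.7, 46.6 ± 8.87 and 45.9 ± 4.47 CPM. On the alternative side, Chil3 and Retnla were abundant at 394 ± 39.0 and 225 ± 51.2 CPM, and Mrc1 and Ccl22 reached 46.2 ± 5.69 and 38.7 ± 9.45 CPM. The exact two-sided sign-flip test gave p = 0.25, its smallest value with 3 mice, and the difference was 1.15 with list means in place of medians. Per kilobase of exon, which allows for transcript length, Nos2 had 77.5 times the summed counts of Arg1, against 153 times without that division.

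**Figure D1:**
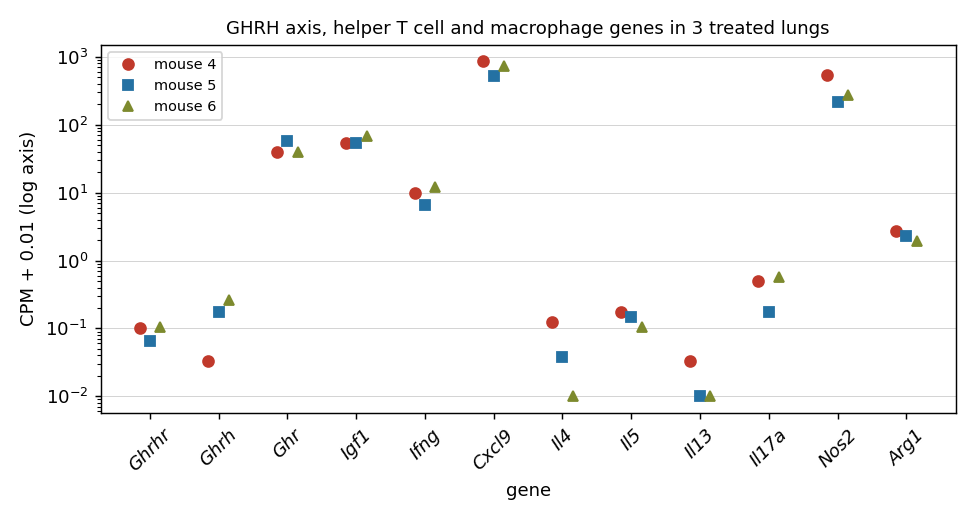
Expression of GHRH axis, helper T cell and macrophage genes in each of the 3 lungs, as CPM + 0.01 on a log axis, with 1 point per mouse. Ghrhr and Ghrh lie near the floor (at most 0.252 CPM) while Ghr and Igf1 lie at 40.0 CPM or above, Ifng lies above Il4, Il5, Il13 and Il17a in each mouse, and Nos2 above Arg1.

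Leading genes of the granuloma and mycobacterial recognition lists were highly expressed. No unchallenged lung was analysed here, so these levels, that of Ace included, do not show that granulomas were present. Saa3, an acute-phase serum amyloid, reached 1788 ± 761 CPM, Gpnmb, a lysosomal glycoprotein of foamy macrophages, 526 ± 202, Ace, whose enzyme is raised in the serum of sarcoidosis patients, 449.5 ± 82.1, and Cd68 345 ± 127. The receptors Clec7a and Clec4e (Mincle, which binds mycobacterial cord factor) stood at 318 ± 59.9 and 280.2 ± 91.2 CPM, Cd36 at 269.6 ± 55.3 and Cd14 at 170.1 ± 40.2. Median members of the granuloma, mycobacterial recognition and class II lists lay at 65.1 ± 12.6, 101 ± 30.5 and 2609 ± 683 CPM. Subunits of the phagocyte oxidase, Cybb and Cyba, had 642 ± 199 and 541 ± 108 CPM, with Sod1 at 338 ± 39.2 and Sod2 at 273 ± 52.0, and the reactive oxygen list had a median of 185 ± 21.1 CPM. Inflammasome and cell death genes had a median of 43.4 ± 2.26 CPM, led by Gsdmd at 128 ± 16.1 and Pycard at 71.0 ± 11.2. Type I interferon response genes had 51.9 ± 5.57 CPM, led by Oasl2 at 211 ± 39.2. The regulatory T cell and checkpoint list lay lower, at 8.45 ± 2.31 CPM, yet its ligand Cd274 (PD-L1) stood at 228 ± 53.1 CPM and Foxp3 at 8.38 ± 2.43.

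Matrix genes were abundant, with Col3a1 at 849 ± 46.4 CPM, Col1a1 at 588 ± 68.4, Col1a2 at 511 ± 25.8 and fibronectin, Fn1, at 358 ± 88.2, and a list median of 145 ± 11.2 CPM. Proliferation genes had a median of 18.2 ± 3.17 CPM, led by Mki67 at 83.9 ± 11.9 and Top2a at 50.1 ± 8.39. The immediate early list had 46.6 ± 1.60 CPM (Junb 248 ± 32.6, Jun 184 ± 23.6), the heat shock list 70.9 ± 7.30 (Hspa8 1485 ± 203) and the glucocorticoid response list 122 ± 26.8 (Lcn2 1173 ± 241, Sgk1 178 ± 41.6). Circadian clock genes had 48.5 ± 9.42 CPM, with Nr1d1 at 121 ± 17.5 and Tef at 120.1 ± 31.9.

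Alveolar type 2, club and alveolar type 1 cell lists had the highest medians of the cell types in CPM as means over the mice, though in mouse 4 the skeletal muscle list (570.5 CPM) lay above the club (512) and alveolar type 1 lists (289). The means were 1479 ± 72.3 CPM for alveolar type 2 cells, 667 ± 168 for club cells and 350.0 ± 96.7 for alveolar type 1 cells, whose receptor gene Ager reached 1969 ± 391.8 CPM. Per kilobase of exon the order differed, with a log2 level of 9.27 for the club list, 8.72 for alveolar type 2, 7.92 for erythroid, 7.18 for skeletal muscle and 6.88 for alveolar type 1. Ciliated and goblet cell lists had 66.9 ± 16.4 and 5.35 ± 1.99 CPM, led by Tppp3 at 332 ± 51.6 and the mucin Muc5b at 72.7 ± 29.0. Of stromal cells, endothelial genes had 167 ± 35.9 CPM (Pecam1 458 ± 75.7), fibroblast genes 132 ± 14.6 (Inmt 624 ± 306), smooth muscle and pericyte genes 114 ± 34.0 (Acta2 143 ± 20.8) and mesothelial genes 12.0 ± 3.28 (Msln 66.6 ± 11.5). Monocyte and interstitial macrophage genes had 190.3 ± 30.8 CPM, led by C1qa at 568 ± 137 and C1qb at 413 ± 98.5, against 31.2 ± 4.50 for alveolar macrophage genes, of which Chil3 and Marco (69.9 ± 21.7) were highest. Ear1 and Ear2 of that list are near-identical copies and their counts are uncertain.

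Transcripts of B, T and plasma cell lists lay well above those of eosinophil, mast cell and basophil lists. These are levels of unlike marker lists and do not measure numbers of cells. B cell, T cell and NK cell lists had medians of 59.6 ± 10.8, 39.8 ± 8.94 and 5.98 ± 0.554 CPM, with Cd79a at 95.3 ± 24.2, Cd4 at 57.1 ± 14.6, Cd3e at 56.7 ± 12.8 and Gzma at 41.5 ± 5.88. Plasma cell genes had 232 ± 18.8 CPM, led by the antibody chains Igkc at 1743 ± 545, Igha at 1241 ± 324 and Ighm at 558 ± 192, a multigene family whose reads can be shared. Dendritic cell genes had 27.2 ± 4.77 CPM (Clec9a 40.4 ± 8.93) and neutrophil genes 33.1 ± 7.66 (Csf3r 92.0 ± 21.6, S100a8 60.2 ± 15.3). Eosinophil genes had 1.43 ± 0.276 CPM, with Siglecf, also made by alveolar macrophages, at 8.75 ± 1.18 and Epx at 0 counts in every library. The mast cell and basophil list had 0.168 ± 0.0668 CPM, led by Cma1 at 1.76 ± 0.241. Blood was seen in Hbb-bs at 1031 ± 513 CPM and in the erythroid list at 182 ± 85.4, and platelet genes had 5.18 ± 1.26 CPM (Itga2b 13.3 ± 5.01). Hba-a1 and Hba-a2, like Hbb-bs and Hbb-bt, are near-identical pairs.

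Markers of other tissues that the lung sample or its dissection could hold differed widely in level. Where these transcripts came from, cardiac muscle genes included, is not shown by their levels. Skeletal muscle genes had a median of 324 ± 214 CPM, cardiac muscle genes 34.8 ± 17.4 and squamous epithelium genes 23.9 ± 16.1. Adipocyte genes had 2.73 ± 1.32 CPM (Cfd 35.2 ± 15.001), thymocyte genes 0.305 ± 0.0717 (Cd1d1 57.9 ± 12.2, Themis 8.35 ± 1.32), thyroid genes 0.775 ± 0.160 (Iyd 2.97 ± 0.921) and cartilage genes 0.119 ± 0.0404 (Comp 0.560 ± 0.177). Over all 47 lists, 32 had a median of at least 10 CPM in each mouse, a level chosen after the data were seen.

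Skeletal muscle and squamous epithelium genes were higher in mouse 4 than in mice 5 and 6, member by member. Acta1, skeletal muscle actin (ENSMUSG00000031972, chromosome 8, 123891769 to 123894751), stood at 1936, 687 and 594 CPM, muscle creatine kinase Ckm at 776, 292 and 258, the myosin Myh1 at 768, 281 and 232 and troponin Tnnt3 at 704, 264 and 228 CPM in mice 4, 5 and 6. Of the keratins of stratified epithelium, Krt13 (ENSMUSG00000044041, chromosome 11, 100117327 to 100121566) had 142, 53.1 and 46.3 CPM, Krt5 88.6, 34.0 and 28.1, Krt4 68.3, 24.3 and 21.1 and Krt15 42.5, 14.96 and 14.1. All 8 skeletal muscle genes and all 7 squamous genes were higher in mouse 4 than in mouse 5 and in mouse 6. The spread of both lists exceeded that of expression-matched random lists (median log2 ratio of spread to trend 5.21 and 5.65, resampling with Benjamini-Hochberg adjusted p = 0.00112 for each, the smallest reached). Cardiac muscle genes also varied more than random lists (5.07, adjusted p = 0.00112), in another order, with Myh6 at 58.9, 22.0 and 76.6 CPM, Tnni3 at 39.8, 26.5 and 61.0, Tnnt2 at 35.2, 14.6 and 57.5 and Actc1 at 153, 73.3 and 82.2. Without mouse 4 the skeletal muscle and squamous calls were lost (adjusted p = 0.457 and 0.473), and the cardiac call was kept.

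Club and ciliated cell genes were lower in mouse 4. Scgb1a1 stood at 7643, 21691 and 19127 CPM in mice 4, 5 and 6, the cytochrome Cyp2f2 at 798, 2111 and 1667, Scgb3a2 at 512, 642 and 846 and Aldh1a7 at 35.96, 78.0 and 68.1, and all 5 club cell genes and all 6 ciliated cell genes were lower in mouse 4 than in either other mouse. Both lists varied more than random lists (adjusted p = 0.00112 and 0.0101), and neither did without mouse 4 (adjusted p = 0.403 for both). Goblet cell genes, also of the airway, were not lower in mouse 4, with list medians of 7.59, 3.82 and 4.64 CPM in mice 4, 5 and 6 (5 of 5 members higher in mouse 4 than in mouse 5 and 3 of 5 than in mouse 6). They varied as well (adjusted p = 0.0241), with Muc5b at 89.5, 39.2 and 89.4 CPM and Clca1 at 16.5, 5.84 and 10.1, and not without mouse 5 (adjusted p = 0.439). Smooth muscle and pericyte genes passed (adjusted p = 0.0343). Tagln was lower in mouse 4 at 75.2, 136 and 132 CPM, but Des, which striated muscle also makes, was higher at 526, 276 and 243. Without mouse 4 this list varied less than random lists (a median log2 ratio of −4.03 from that of the median random list, adjusted p = 0.0365). With DESeq2 dispersions the list missed the threshold (adjusted p = 0.0987), though its excess over the median random list was 2.01 against 2.28. The alveolar type 2 list did not stand apart (adjusted p = 0.9995), nor did the fibroblast list (0.187).

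**Figure D2:**
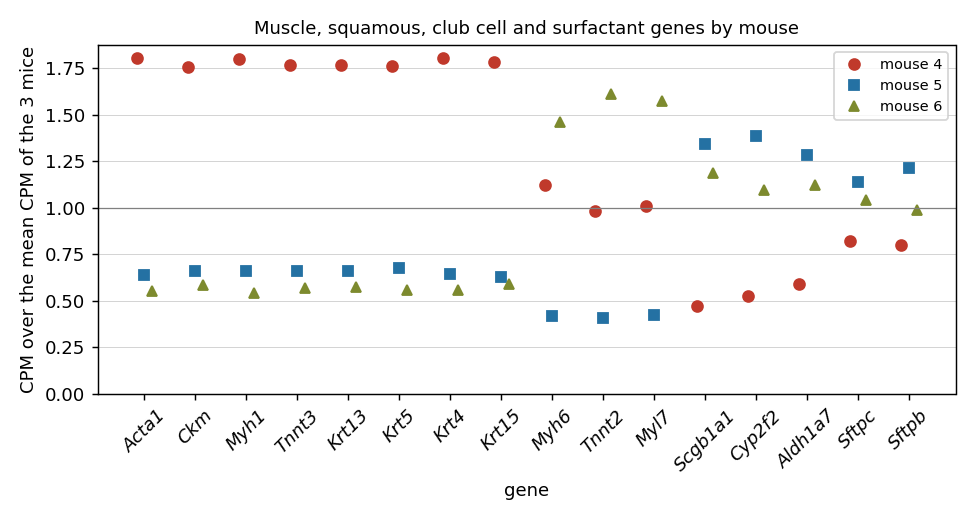
CPM of 16 genes in each mouse, divided by the gene's mean over the 3 mice, with 1 point per mouse and a line at 1. The genes were picked after their values were seen. Skeletal muscle and squamous genes (Acta1 to Krt15) are highest in mouse 4 and cardiac muscle genes (Myh6, Tnnt2, Myl7) in mouse 6. Club cell genes (Scgb1a1, Cyp2f2, Aldh1a7) are lowest in mouse 4.

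Granuloma, mycobacterial recognition and monocyte genes were higher in mouse 4, and blood and vessel genes in mouse 5. Saa3 had 2643, 1187 and 1535 CPM in mice 4, 5 and 6, Gpnmb 759, 398 and 419.7, Cd68 488, 247 and 300.5 and Clec4e 384, 215 and 241, and 15 of 18 granuloma genes were higher in mouse 4 than in mouse 5 and 13 than in mouse 6. Not every myeloid list was higher in mouse 4. Alveolar macrophage and alternative activation medians were lowest there, at 27.1, 30.6 and 36.03 CPM and 7.90, 10.7 and 9.19 CPM. Neither list stood apart from random lists in spread (resampling, adjusted p = 0.853 and 0.0770). Of 10 alternative activation genes, 5 were higher in mouse 4 than in mouse 5 and 3 than in mouse 6. Of 7 dendritic cell genes, 5 were higher in mouse 4 than in mouse 5 and 0 than in mouse 6. Neutrophil medians were 36.3, 38.6 and 24.3 CPM. Spread above random lists was found for the granuloma (0.00112), mycobacterial recognition (0.00375), classical activation (0.0176), reactive oxygen (0.0101), and monocyte and interstitial macrophage lists (0.0101, adjusted p in each case). Hbb-bs stood at 723, 1624 and 747 CPM and Alas2, the erythroid heme synthesis enzyme, at 19.8, 40.5 and 21.2, and the vessel genes Cldn5 and Vwf at 186, 303 and 207 and 122, 207 and 157. Erythroid, endothelial, platelet and alveolar type 1 lists passed with adjusted p of 0.00112, 0.00375, 0.0166 and 0.0241. Without mouse 5 these 4 calls were lost, with adjusted p of 0.890, 0.439, 0.767 and 0.890, the last with its direction turned (−0.42 from the median random list). Without mouse 6 the alveolar type 1 list missed the threshold (0.0504) though its excess over the median random list was larger, at 3.00 against 2.54 with all mice. Of the granuloma and macrophage lists that passed, the granuloma call was kept without any 1 mouse. Mycobacterial recognition was lost without mouse 4 (0.239), classical activation and reactive oxygen without mouse 5 (0.586 and 0.125), and monocytes without mouse 4 or 5 (0.108 and 0.119). The excess over the median random list fell from 2.37 to 1.29 and from 2.03 to 0.84 for recognition and classical activation, but less for reactive oxygen (2.37 to 1.96) and monocytes (2.64 to 1.99 and 2.20), where 2 samples were left for the test.

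The T cell genes Cd4 and Cd8a and the chemokine Cxcl9 were lowest in mouse 5. Cd4 stood at 64.7, 40.3 and 66.2 CPM and Cd8a at 25.1, 22.8 and 40.0 in mice 4, 5 and 6, and Cxcl9 at 858, 518 and 732. The NK cell list was lowest in mouse 4, with medians of 5.48, 5.89 and 6.57 CPM. Plasma cell medians were 237, 248 and 211 CPM, though 8 of 9 members were higher in mouse 4 than in mouse 5. T cell, B cell, dendritic cell, and Th1 and interferon-gamma lists varied more than random lists (adjusted p = 0.00112, 0.0200, 0.0155 and 0.00112), and all 4 calls were lost without mouse 5 (0.767, 0.439, 0.980 and 0.770). Adipocyte genes passed (0.00270) and were lost without mouse 5 (0.770), plasma cell genes (0.00623) and clock genes (0.00200) without mouse 4 (0.0843 and 0.488), and neutrophil genes (0.0138) without mouse 6 (0.869). The excess of the clock list fell from 2.77 to 0.84, and that of the plasma cell list only from 2.90 to 2.18. Mesothelial (0.0166) and glucocorticoid response lists (0.0211) were lost without mouse 4 (0.159 and 0.345) or mouse 6 (0.115 and 0.0727). Their excess over the median random list was 2.70 and 2.40 with all mice, 2.33 and 1.51 without mouse 4, and 2.61 and 2.67 without mouse 6, where the size was near or above that with all mice and only 2 samples were left. Of 45 lists tested, 26 thus passed, all above random lists, and 2 of the 26, cardiac muscle and granuloma, passed under every alternative tried. Members of a list tend to vary together within a mouse, which makes these p-values too small, and they describe these 3 libraries.

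In all, 19 lists, alveolar type 2 and fibroblast included, did not stand apart from random lists in their spread between mice. Among question lists the adjusted p was 0.296 for the GHRH axis, 0.916 for Th2, 0.935 for Th17, 0.0767 for regulatory T cell and checkpoint genes, 0.161 for inflammasome and cell death, 0.618 for matrix and 0.108 for class II genes. It was 0.0770 for both alternative activation and type I interferon response, 0.398 for cell cycle, 0.184 for immediate early and 0.195 for heat shock genes. Among cell types it was 0.853 for alveolar macrophages, 0.935 for eosinophils, 0.850 for NK cells, 0.647 for thymocytes and 0.897 for thyroid. The mast cell and basophil list and the cartilage list had 1 tested member each and were not tested.

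**Figure D3:**
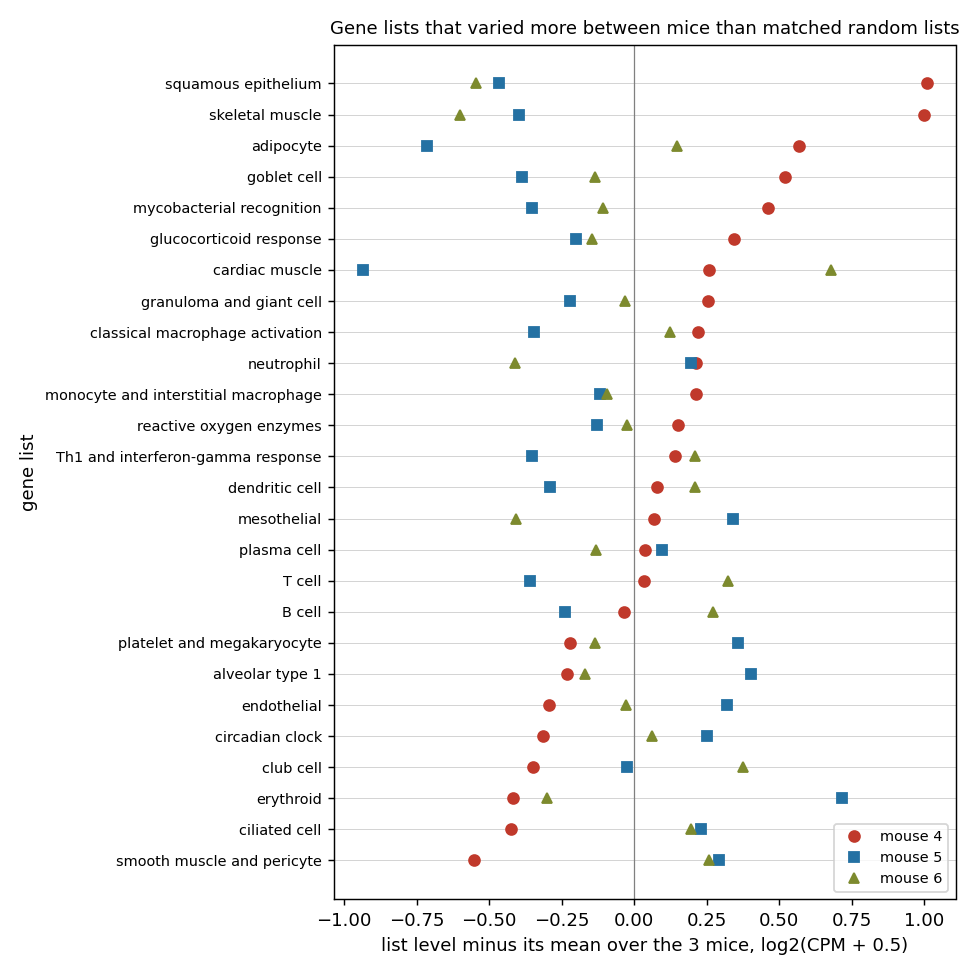
Level of each of the 26 gene lists that varied more between mice than random lists, as the list's median log2(CPM + 0.5) in 1 mouse minus its mean over the 3 mice, with 1 point per mouse. Mouse 4 lies at 1.01 for the squamous list, and mouse 5 at 0.72 for the erythroid list.

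Gene by gene, Bpifa1 and striated muscle genes had the smallest p for spread between mice, and none passed the test. Bpifa1, a secreted protein of the upper airway (ENSMUSG00000027483, chromosome 2, 154142880 to 154149219), stood at 15.7, 7.74 and 50.4 CPM in mice 4, 5 and 6. Among the 10 genes with the smallest p were Xirp2, Neb, Actn3, Mybpc1, Myom2 and Eef1a2, known from striated muscle (the last also made in neurons), with Neb, nebulin, at 179, 69.1 and 50.8 CPM, and also the keratin Krt4 and Mir6236, at 123, 45.4 and 187 CPM, which can hold ribosomal RNA reads. All 10 failed, with an adjusted p of 0.806. By edgeR's quasi-likelihood dispersion against its trend, 0 of 17636 genes passed an adjusted p of 0.05, and 867 had an unadjusted p under 0.05, against 882 by chance. The trend and prior degrees of freedom of this F test were fitted to these same genes, which draws such a count towards that by chance. Its closeness to 882 therefore does not show that excess spread was absent. Adjusted over the list alone, 39 list members passed in 9 lists, among them all 8 of skeletal muscle, all 8 of cardiac muscle, 6 of 7 erythroid, 5 of 6 squamous and 4 of 5 club cell genes. Adjusted over all genes, 0 list members passed. The adjustment over single lists was not in the design and does not control error over the lists together. Members that vary together within a mouse are not separate findings. The biological coefficient of variation over all genes was 0.160. Limma called 0 genes and the F test without mouse 4 called 13, both at an adjusted p under 0.05. DESeq2 flagged 102 genes as dispersion outliers against its trend, a rule that gives no p-value. On simulated counts with the spread fitted here the F test found 0 of 50 genes shifted 16-fold in 1 mouse, so a count of 0 does not show that genes were level.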

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

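The chi-square test against the trend alone and the level of 10 CPM were chosen only after the results were seen, and the adjustment over single lists was not in the design. The count of genes with excess spread was 0 by edgeR's F test and stayed 0 with other scaling, a 1 CPM filter, non-robust estimation and limma. It was 629 with no filter on low counts, of which the main test also held 608, and the median of their mean CPM was 30.2. DESeq2 flagged 102 genes as dispersion outliers, a rule without a p-value and so not a like count. The chi-square test called 278, and on simulated counts it called 187 unshifted genes where these had the fitted spread and 4 where they lay on the trend, against 0 and 9 by the F test. Leaving out each mouse gave 0 to 13 genes, with 13 only without mouse 4. The cause of these differences was not tested. Lists past the threshold numbered 26 to 31 with all mice and 14 to 24 with 1 mouse left out (18, 14 and 24 without mouse 4, 5 and 6), where 2 mice leave fewer samples. With 1 mouse left out, the log2 excess over the median random list ran from −1.63 (without mouse 4) to 4.14 for the ciliated list, −4.03 (without mouse 4) to 3.96 for smooth muscle and −0.42 (without mouse 5) to 3.52 for alveolar type 1, and smooth muscle was lost with DESeq2. The biological coefficient of variation was 0.137 to 0.186 with 1 mouse left out. Th2 minus Th17 turned to −0.76 with tested members, −0.086 with list means and −0.45 with shared members left out, and ran from −0.043 to 0.12 with 1 mouse left out. The other 3 list differences kept their sign under every alternative, with an exact p that cannot pass. No paired analysis was possible because the samples form 1 group. Depth limits the genes with few counts, such as Ghrhr, Il4 and Il13.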

Other observations

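The values of single genes and shares in the next 2 paragraphs were picked after they were seen, as were the tests of tracheal cartilage, of dilution of the lung epithelium, of goblet cell genes, of ciliated cell shifts, of the other leukocyte lists and of the first lists given further on, and the rule that the tests of 1 explanation are read together. Read alone, the first lists of muscle and squamous genes and the second lists of airway genes would each have met their prediction. Bootstrap intervals below were drawn over list members within 1 pair of mice, so they show spread among genes and not among mice. What they argue against is limited to these libraries. Dbp, a transcription factor driven by the clock, was lower in mouse 4 at 38.4, 90.9 and 83.6 CPM in mice 4, 5 and 6, as was Tef at 84.8, 147 and 129, while Per1 was higher in mouse 4 at 71.1, 51.9 and 50.0. Bpifb1 and Scgb3a1 were highest in mouse 6, at 93.3, 35.0 and 114 and 363, 153 and 508 CPM, as was the detoxifying enzyme Cyp1a1 at 2.88, 4.37 and 16.2. Without mouse 4, Bpifa1 and Bpifb1 passed edgeR's F test for spread (adjusted p = 0.00868 and 0.0266), as did the cardiac muscle genes Tnnt2 (0.0255) and Myh6 (0.0266).

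The antibody genes named here, the B cell chemokine Cxcl13 and the cytokine Il21 had counts in all 3 lungs, Cxcl13 at 48.2, 33.6 and 43.9 CPM, Ighg1 at 179.8, 99.1 and 180.0, Ighg3 at 18.8, 10.4 and 37.3 and Il21 at 1.44, 0.885 and 1.77. Features over ribosomal RNA loci took 0.440%, 0.214% and 0.720% of the counts of mice 4, 5 and 6. The perinatal muscle myosin Myh8 stood at 1562, 558 and 469 CPM and H19 at 443, 153 and 122.

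Skeletal muscle and squamous epithelium genes were higher in mouse 4. A squamous change of the airway lining as the only source of both was argued against, since second lists of genes fixed before the test gave a skeletal muscle shift 1.16 times the squamous shift (bootstrap interval 0.809 to 2.16). The first lists had already shown muscle genes higher in mouse 4, so this outcome could be foreseen and adds little. A squamous change beside a separate source of muscle genes was not tested and stays open. Tracheal tissue with cartilage stays open. Cartilage counts were 0.304%, 0.501% and 0.897% of squamous counts in mice 4, 5 and 6, and so lowest in mouse 4. They lay near the floor, at 50, 26 and 35 counts, and the share that such tissue would give was not measured. Another candidate source, 1 piece of neighbouring tissue holding both striated muscle and squamous epithelium, stays open as well. Shifts of the first lists differed by at most 0.0445 on the log2 scale (intervals −0.0993 to 0.684 over mouse 5 and −0.0543 to 0.694 over mouse 6). Those of the second lists differed by at most 0.329, above the 0.3 allowed, with an interval of −0.268 to 0.847. These intervals all reach past 0.3. No other biological explanation was tested, because the samples form 1 group.

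Club cell genes were lower in mouse 4. Dilution of all lung epithelium as the only cause was argued against, since the club cell shift lay −0.992 from that of alveolar type 2 genes over mouse 5 (interval −1.26 to −0.0363), and −0.834 over mouse 6 with an interval of −1.25 to −0.557. Alveolar type 2 genes were not level, with median shifts of −0.275 over mouse 5 and −0.0780 over mouse 6. Of these 8 genes, 1 was higher in mouse 4 than in mouse 5, and 1 than in mouse 6. A smaller dilution beside an airway change thus stays open. A loss of every conducting airway cell type alike was argued against, since club and goblet cell shifts differed by −2.17 over mouse 5 (interval −2.69 to −1.23), and a change of club cells alone was as well, since both ciliated cell lists shifted by −0.536 or further below 0 in each contrast, with whole intervals below 0. Less conducting airway along with more goblet cell transcripts may account for it. That cannot be told apart from a change of both club and ciliated cells. The median goblet cell shift was 0.906 over mouse 5 but 0.000557 over mouse 6. Second club and ciliated lists differed by −0.0498 over mouse 5 and −0.0773 over mouse 6, with intervals that span 0. The first lists differed by −0.695 over mouse 5 (interval −0.991 to 0.246) and −0.376 over mouse 6 (−0.804 to −0.177). The last interval lies wholly below 0, so first and second lists together do not settle whether club and ciliated genes fell alike. No other biological explanation was tested, because the samples form 1 group.

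Granuloma and monocyte genes were higher in mouse 4, and alveolar macrophage genes were not. More leukocytes of every kind than in mouse 6 was argued against, since 3 of 8 other leukocyte lists (dendritic, T and NK cell) were lower in mouse 4 with their whole bootstrap intervals, while neutrophil and plasma cell lists were higher, and the myeloid shift exceeded that of lymphocytes by 0.380 for the second lists (interval 0.0194 to 0.659) and 0.417 for the first (0.141 to 0.654). More leukocytes of every kind than in mouse 5 stays open, since 0 of 8 lists lay wholly below 0 and 3 wholly above (T, B and plasma cell), and myeloid and lymphocyte shifts differed by 0.0892 (interval −0.0716 to 0.329) and 0.102 (−0.117 to 0.353). Greater depth of the library of mouse 4 leaves expected CPM as they were, so depth by itself would not give this shift. Thinning every library to the smallest total gave 1.05 times the granuloma shift over mouse 5 (interval 0.930 to 1.13). That outcome follows from the scaling and adds no support. No other biological explanation was tested, because the samples form 1 group.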
